A study of Mus musculus with 16 samples.

How the data were processed

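Peritoneal macrophages of mice were sorted by flow cytometry into LPM and SPM, with and without bacteria, after injection of E. coli, in an arm without RA (Ecoli) and an arm with RA injected 24 hours before the bacteria (RE). Per the labels, SPM and LPM were told apart by staining for F4/80 and by uptake of bacteria. RNA was extracted with TRIzol, and libraries were made with the SMART-Seq v4 Ultra Low Input kit and sequenced on a NovaSeq X Plus. Per the file headers, each file held 1 whole-number count per gene symbol for 1 library, and the authors' processing notes named FastQC, MultiQC, fastp and the mm10 genome build. Tool versions, aligner, counting tool, strandedness, annotation and the time between infection and sorting are not given in the sources used here. The 16 files had the same 24198 symbols, of which 22427 stood in the reference name table used here, and 0 symbols of mitochondrial genes. Coordinates are those of GENCODE vM21 on GRCm38, the assembly of mm10. Strandedness was not tested, so genes that overlap on opposite strands can share reads.

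Total counts were 23.5 to 41.9 M per library (median 36.6 M), the 10 most abundant genes took 8.56% to 27.4% of the counts, and TMM factors ran from 0.675 to 1.68. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 15260. In R 4.3.3, edgeR 4.0.16 fitted a quasi-likelihood model with TMM normalisation, robust dispersions and 8 groups of 2 libraries, with 8 residual degrees of freedom. The 12 contrasts covered the effect of RA (averaged, in LPM, in SPM), of cell type (averaged, without RA, with RA), of uptake (averaged, in LPM, in SPM) and the 3 differences between effects. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. CPM values in the text use the TMM library sizes, and sums over marker genes of other cells are in CPM.

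Gene lists of 693 genes in 31 groups (685 in the files) were fixed beforehand, covering macrophage identity, retinoid biology, uptake and killing of bacteria, cytokines and interferon, metabolism, stress, proliferation and other cell types. Lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over the 31 lists, and again with the correlation estimated from the data and with fry. Crabp1, Ddx58, Ero1l, Atp5f1a, Atp5f1b, Hist1h1b, Trac and Trbc1 were absent from the files under these symbols. The design, the lists, the contrasts, the threshold, the alternatives not said to be added later and the rule for named genes were chosen before the data were examined. By that rule, the averaged contrasts name the 6 largest changes each way with adjusted p under 0.05, an average of at least 3 log2 CPM and the same sign in all 4 strata, without predicted genes. Other contrasts name the 4 largest each way and 2 members of at most 8 lists. In the averaged contrasts up to 3 members with the lowest p were named for each list with at least 3 changed genes or a camera adjusted p under 0.05, and some macrophage and RA genes were always followed (Gata6, Adgre1, Timd4, Icam2, H2-Ab1, Ccr2, Rarb, Cyp26a1, Cyp26b1, Dhrs3, Arg1, Marco, Il1b and Nos2).

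Alternatives were DESeq2 size factors within edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with quality weights, models with the replicate number as a block, models of the compared libraries alone, counts summed per arm and number, and omission of each library in turn. After the data were seen, omission of the RE libraries of number 2, of the Ecoli SPM BAC- libraries, and of the former with the library labelled Ecoli SPM BAC+ 2 were added, as were the nested block without that library and comparisons within single strata. All 16 libraries stayed in the model under their labels.

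The procedure was tested on simulated data, drawn from the means and dispersions of the real genes and the sizes of the real libraries, with changes of 1 or 3 on the log2 scale put into 200 genes. Of genes changed by 1, 19.6% were recovered for RA averaged, 1.04% for RA in LPM, 0% for uptake in SPM and 7.29% for cell type averaged. Of genes changed by 3, the shares were 76.3%, 49% (RA in LPM), 56.8% and 77.1%. False calls were 13 of 105, 2 of 50, 7 of 61 and 6 of 87. Small effects were thus mostly out of reach. A list shifted on purpose had a camera adjusted p of 4.16e-62, and 0 of 29 other lists were called. Genes and libraries were simulated as independent, so these runs do not show how the tests behave where genes or libraries vary together. In the real data 17 of 31 lists were called for RA averaged at the preset correlation and 0 with the estimated correlation.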

Results

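Gene expression was measured by RNA sequencing in macrophages sorted from the peritoneal cavity of mice that had received E. coli. The cavity holds large peritoneal macrophages (LPM), the resident population, which carry much F4/80, the surface protein encoded by Adgre1, and small peritoneal macrophages (SPM), which carry less of it and are replenished from blood monocytes. The bacteria carried a plasmid for a red fluorescent protein, so cells that had taken up bacteria (BAC+) could be sorted apart from cells that had not (BAC-). Each mouse received 10000000 colony-forming units in the peritoneal cavity, and in the retinoic acid (RA) arm RA was injected 24 hours earlier. RA is the active form of vitamin A, a ligand of nuclear receptors. The 16 libraries formed 8 groups of 2, one for each combination of arm, cell type and uptake. Titles with Ecoli were taken as bacteria without RA and titles with RE as RA and bacteria, which the labels do not spell out. In each library, 14088 to 18158 genes had at least 1 count. Log2 fold changes are given ± SE and group means ± SD, in normalised CPM, counts scaled to the library size. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

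Adgre1 was the sort marker and was examined first. In the Ecoli arm it read 2159 and 2287 normalised CPM in LPM BAC+ and 2761 and 2917 in LPM BAC-. It read 197 and 92.1 in SPM BAC- and 265 in Ecoli SPM BAC+ 1. The library labelled Ecoli SPM BAC+ 2 read 2775, which goes against its label. In that library Gata6, the transcription factor that sets LPM identity, read 45.8 and Timd4, a receptor for phosphatidylserine on resident macrophages, 1224. The other Ecoli SPM libraries held 0.710 to 2.09 for Gata6 and 26.3 to 198 for Timd4. The 4 Ecoli LPM libraries held 30.3 to 43.0 and 1871 to 2304. In the RE arm, the LPM libraries of number 1 held 2885 and 3114 for Adgre1. Those of number 2 held 635 and 589, within the RE SPM range of 407 to 737, which goes against their label too. Gata6 read 35.7 and 44.6 in RE LPM number 1 and 0.737 and 1.34 in RE LPM number 2. Ccr2, the chemokine receptor of blood monocytes, went the other way, with 126 and 110.4 in number 1 and 1240 and 1408 in number 2. Xist stayed at or below 0.2 CPM and 4 genes of the Y chromosome were read in all 16 libraries, as in male mice.

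**Figure D1:**
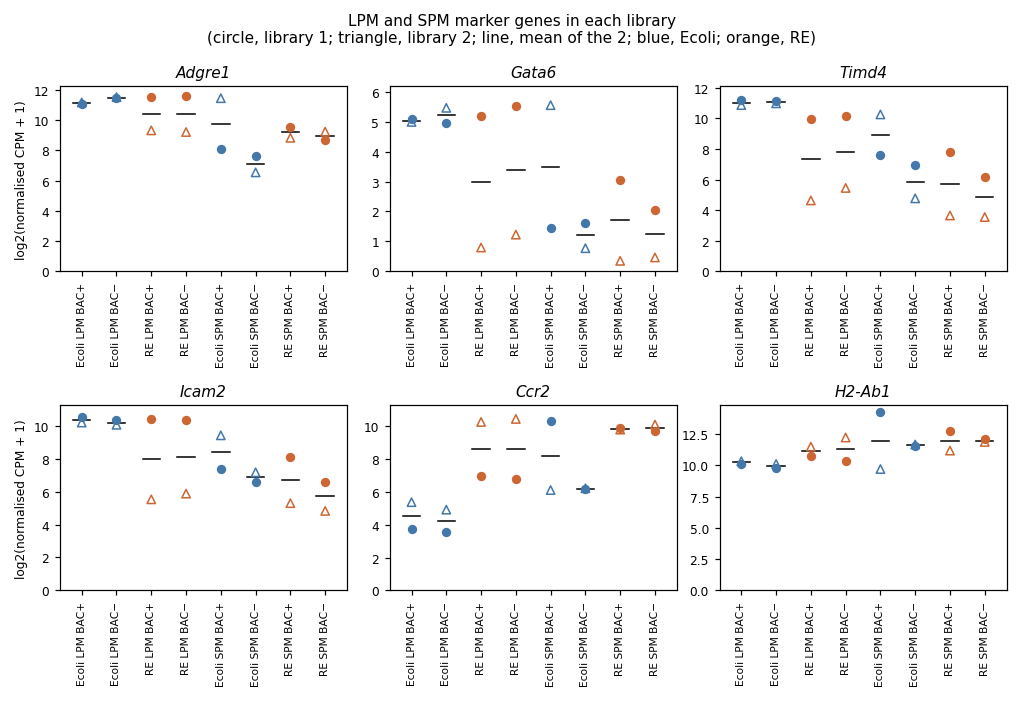
Expression of 6 marker genes as log2(normalised CPM + 1) on the vertical axis, by group on the horizontal axis, with a circle for library 1, a triangle for library 2 and a line at the mean, blue for Ecoli and orange for RE. The library labelled Ecoli SPM BAC+ 2 lies at LPM levels of Adgre1 (2775 CPM) and Gata6 (45.8 CPM), and both RE LPM libraries of number 2 lie low in Gata6 (0.737 and 1.34 CPM).

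RNA of other cells was not spread evenly. The summed CPM of 19 B cell genes was 23370 and 37960 in the Ecoli SPM BAC- libraries and 11350 in RE SPM BAC- 1, and at most 4298 in the other 13. The neutrophil genes summed to 13510 in Ecoli SPM BAC- 2, 7109 in RE SPM BAC+ 1 and 6106 in RE SPM BAC- 1. In Ecoli LPM they summed to 415.1 to 1180 and in RE LPM to 1619 to 3484. Eosinophil genes reached 981 and dendritic cell genes 1372 in Ecoli SPM BAC+ 1, against at most 22.25 and 229.1 in Ecoli LPM. Part of the B cell and neutrophil lists was also read in libraries sorted as LPM. In Ecoli LPM 14 of the 19 B cell genes and 10 of the 18 neutrophil genes had a mean of at least 10 CPM. Whether macrophages or other cells in the gate gave these reads was not tested.

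**Figure D2:**
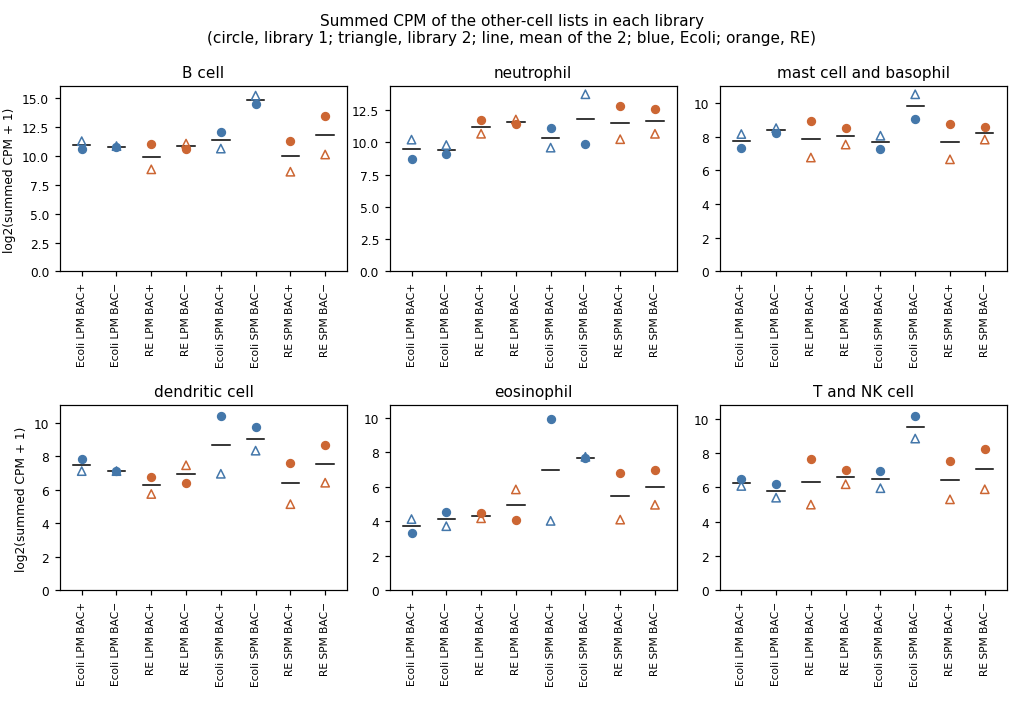
Summed CPM of marker genes of other cell types per library, as log2(summed CPM + 1) on the vertical axis, by group on the horizontal axis, with a circle for library 1, a triangle for library 2 and a line at the mean, blue for Ecoli and orange for RE. B cell genes were highest in the Ecoli SPM BAC- libraries, at 23370 and 37960 CPM.

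The RE and Ecoli libraries were compared to learn how macrophages that meet bacteria differ with RA, first averaged over both cell types and both uptake classes. With RA, Trem1, Chil3, Acod1 and Treml4 rose and Cd209a fell. Trem1, a receptor that amplifies inflammatory signals in myeloid cells, averaged 492 ± 71.6 (SD, n = 8) normalised CPM in RE and 139 ± 73.5 (SD, n = 8) in Ecoli, a log2 fold change of 2.04 ± 0.20. Chil3, a chitinase-like protein secreted by macrophages and monocytes, ranged from 3.66 to 41.4 in Ecoli and from 90.3 to 909.5 in RE. Acod1, the enzyme that makes itaconate, rose from 902 ± 565 to 3774 ± 1884. Treml4, a receptor of the TREM family, rose from 2.42 ± 2.19 to 34.8 ± 19.6. Cd209a, a lectin of the DC-SIGN family, fell by 3.20 ± 0.67 on the log2 scale, with 57.8 to 1154 in Ecoli and 2.84 to 35.6 in RE. For each of these 5 genes, all 8 RE libraries lay beyond all 8 Ecoli libraries. The adjusted p from edgeR's quasi-likelihood test was 0.000671 for Trem1, 0.000671 for Treml4, 0.00228 for Chil3, 0.00958 for Acod1 and 0.0295 for Cd209a. In GRCm38 coordinates, Trem1 and Treml4 are neighbours (chromosome 17, 48232768 to 48246924, and 48264295 to 48275360). Chil3 lies on chromosome 3, 106147554 to 106167564, Acod1 on chromosome 14, 103046977 to 103056573 and Cd209a on chromosome 8, 3743397 to 3748984.

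**Figure D3:**
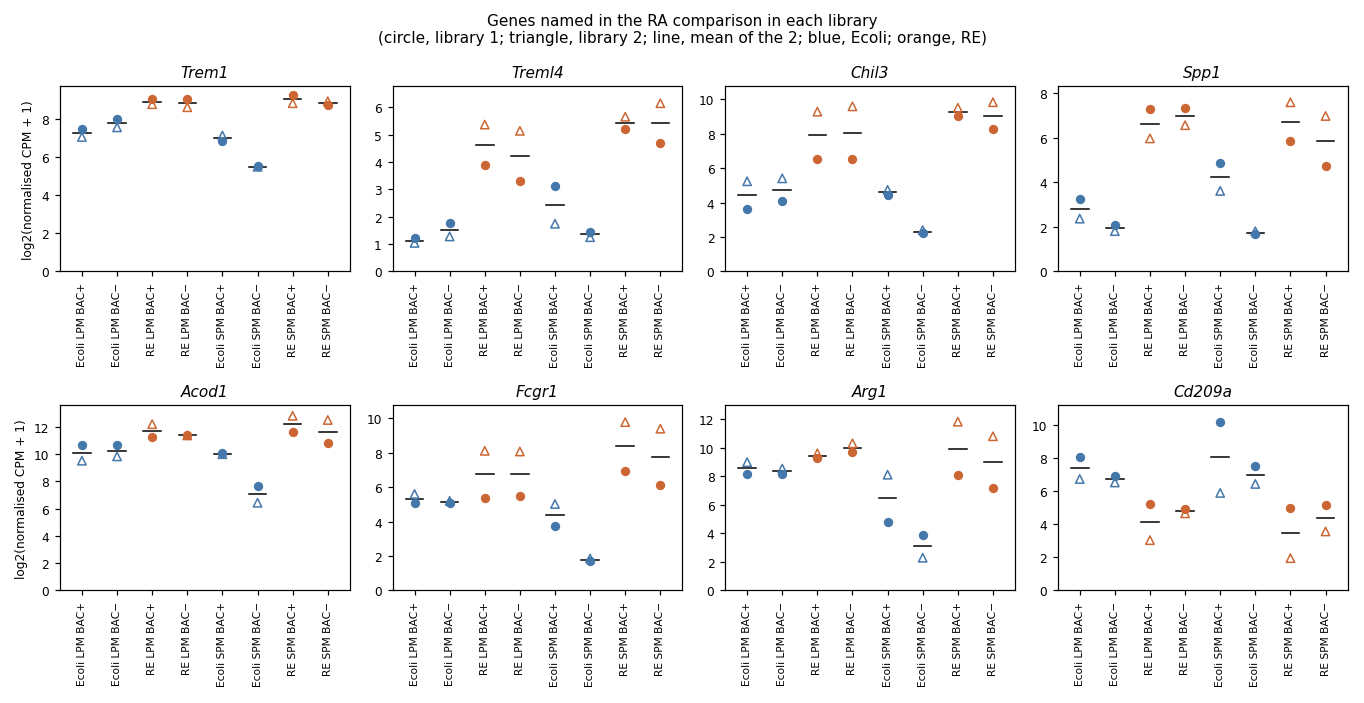
Expression of 8 genes that changed with RA in at least 1 comparison, as log2(normalised CPM + 1) on the vertical axis, by group on the horizontal axis, with a circle for library 1, a triangle for library 2 and a line at the mean, blue for Ecoli and orange for RE. Trem1 ranged from 398 to 620.4 CPM in the 8 RE libraries and from 44.5 to 263 CPM in the 8 Ecoli libraries.

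In all, 461 genes rose and 86 fell with RA among 15260 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment at 0.05, DESeq2 2130, voom 360). The largest rises among genes with an average of at least 3 log2 CPM were Ly6a2 (5.78 ± 0.61), Ifi44, induced by interferon (5.37 ± 0.97), Ms4a4a, a membrane protein of macrophages (5.11 ± 0.88), Chil3 (4.95 ± 0.58). They were followed by Mmp14, a membrane-bound matrix protease (4.55 ± 0.70), and Spon1, a matrix protein (4.41 ± 1.02). The 6 genes had edgeR adjusted p of 0.00107 to 0.0392. Ly6a2 rested on low counts (28.9 ± 32.0 against 0.665 ± 0.728 normalised CPM), and reads of the Ly6a and Ms4a families can be shared between members, so both are uncertain. The largest falls were Cpa3, a mast cell protease (-3.21 ± 0.71), Cd209a (-3.20 ± 0.67), Apoc1, an apolipoprotein (-2.95 ± 0.64), Epha4, a receptor tyrosine kinase (-2.80 ± 0.68). Igf1, a growth factor overlapped by an antisense gene (-2.53 ± 0.57), and Rgs2, a regulator of G protein signalling (-1.75 ± 0.35), came next, all 6 with edgeR adjusted p of 0.0216 to 0.0449. All 8 RE libraries lay beyond the Ecoli mean for these 12 genes except Spon1, with 7 of 8. Beyond every Ecoli library lay 0 of 8 for Cpa3, 3 of 8 for Epha4 and Igf1, and 6 to 8 of 8 for the rest. Cpa3 read 55.9 and 286 normalised CPM in the Ecoli SPM BAC- libraries and 0 to 47.0 in the other Ecoli libraries. Without regard to the model, 45 genes were higher and 16 lower in all 8 RE libraries than in all 8 Ecoli libraries, where chance gives 0.00777% of genes each way, or 1.19 genes, if the libraries are independent. That number is too low for libraries that deviate together, as RE libraries of a number did.

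Of the gene lists fixed in advance, the monocyte list had the lowest p with RA. Of its 16 genes 9 rose and none fell (11 adjusted over the list alone), with a median log2 fold change of 1.97 (camera adjusted p = 1.06e-12, adjusted p = 0.151 with an estimated correlation). Its members Treml4 (4.01), Sirpb1c (2.63) and Ccr2 (3.54) rose, with edgeR adjusted p of 0.000671, 0.0134 and 0.027. For Ccr2, 6 of 8 RE libraries lay above the Ecoli mean. In both RE LPM libraries of number 2, 9 of the 16 monocyte genes lay above every other LPM library. Of the 30 actin and phagocytic cup genes 6 rose (19 adjusted over the list alone), among them the Src-family kinase Fgr (1.68) and the myosin Myo1f (1.60). The list median was 0.64 (camera adjusted p = 7.39e-09, adjusted p = 0.366 with an estimated correlation). Of the 18 neutrophil markers 2 rose (9 adjusted over the list alone), namely Trem1 and Mrgpra2b (2.35), which has a near-identical relative. Over the list the genes had a median of 1.52 (camera adjusted p = 4.87e-08, adjusted p = 0.366 with an estimated correlation).

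Some interferon genes rose with RA, most of all in the RE SPM libraries of number 2. Of 29 type I interferon genes 5 rose (13 adjusted over the list alone), including the oligoadenylate synthetase family members Oas3 (3.07 ± 0.58, all 8 RE libraries above all Ecoli libraries) and Oasl2 (2.14 ± 0.45). The median over the list was 1.17 (camera adjusted p = 5.04e-08, adjusted p = 0.509 with an estimated correlation). Its median was 0.16 in LPM BAC+, 0.27 in LPM BAC-, 2.05 in SPM BAC+ and 2.54 in SPM BAC-. Without the RE libraries of number 2 the type I interferon response list had a median of 0.04 (camera adjusted p = 0.0845). Oas3 read 229 and 394 normalised CPM in the RE SPM libraries of number 2, 14.7 to 37.5 in the other RE libraries and 2.17 to 13.6 in Ecoli. Ifi44 read 59.1 and 81.2 in those of number 2 and 1.38 to 4.13 in the other RE libraries. Of 26 interferon gamma genes 6 rose (15 adjusted over the list alone), among them Batf2 (3.03), Gbp2 (1.96) and the peptide transporter Tap1 (1.84). As a list they had a median of 1.15 (camera adjusted p = 7.99e-08, adjusted p = 0.366 with an estimated correlation), and of 0.51 without the RE libraries of number 2 (camera adjusted p = 0.000127). Batf2 and Tap1 overlap other genes, and guanylate-binding proteins such as Gbp2 have close paralogs. Of 23 glycolysis and hypoxia genes 6 rose (14 rose and 2 fell, adjusted over the list alone). Across the list the median was 0.84 (camera adjusted p = 3.49e-06, adjusted p = 0.366 with an estimated correlation). They included Slc16a3, a lactate exporter, at 270 ± 87.6 against 77.3 ± 43.3 normalised CPM, the hexokinase Hk3 (2.13 ± 0.31) and Ndrg1 (2.33 ± 0.43), with edgeR adjusted p of 0.00456, 0.00958 and 0.0161.

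Some receptors that sense or bind bacteria also rose. Of 29 pattern recognition genes 6 rose (13 adjusted over the list alone), including the lipopeptide receptors Tlr6 (1.37 ± 0.23) and Tlr1 (2.35 ± 0.46) and the adaptor Ticam2 (1.13, which overlaps Tmed7). Their median was 0.67 (camera adjusted p = 5.62e-06, adjusted p = 0.366 with an estimated correlation). Of 30 phagocytic and scavenger receptors 8 rose and 1 fell (14 and 2 adjusted over the list alone). The list median was 0.70 (camera adjusted p = 0.000639, adjusted p = 0.366 with an estimated correlation). Fcgr1, the high-affinity receptor for IgG, averaged 298 ± 316 against 24.6 ± 16.8 normalised CPM. It read 269 to 883 in the RE libraries of number 2. In RE LPM number 1 it read 41.0 and 44.3, within the 32.2 to 47.7 of Ecoli LPM. In RE SPM number 1 it read 123 and 69.1, against 2.19 to 31.5 in Ecoli SPM. Fcgr4 rose by 1.59 ± 0.28 and Scarb1, the HDL receptor, by 1.68 ± 0.27 (edgeR adjusted p of 0.014 for Fcgr1, 0.015 and 0.0131). Of 19 antimicrobial genes 5 rose (9 rose and 1 fell, adjusted over the list alone), Acod1, haptoglobin (Hp, 1.31) and the iron-sequestering Lcn2 (2.14) among them. Over the list the genes had a median of 0.48 (camera adjusted p = 0.000183, adjusted p = 0.366 with an estimated correlation). Lysosome and phagosome genes had 2 of 35 risen (6 rose and 1 fell, adjusted over the list alone). The median over the list was 0.37 (camera adjusted p = 0.0062, adjusted p = 0.611 with an estimated correlation). NF-kB feedback genes had 1 of 23 risen (5 adjusted over the list alone). As a list they had a median of 0.44 (camera adjusted p = 0.00531, adjusted p = 0.447 with an estimated correlation). The lysosome median was -0.29 in LPM BAC+, -0.36 in LPM BAC-, 0.33 in SPM BAC+ and 1.71 in SPM BAC-, the stratum whose Ecoli libraries held the most B cell RNA. In the same order the phagocytic receptor median was -0.29, -0.31, 0.02 and 2.71, and the pattern recognition median 0.14, 0.02, 0.48 and 1.84. The NF-kB feedback median was -0.15, -0.46, 0.54 and 1.51, and the antimicrobial median -0.20, 0.28, 0.67 and 1.71. Without the Ecoli SPM BAC- libraries the phagocytic receptor median was -0.09 (camera adjusted p = 0.369) and the lysosome median -0.09 (camera adjusted p = 0.0919).

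Markers of the 2 macrophage types did not move as a block. Of 24 SPM and antigen presentation genes 5 rose and 1 fell (6 and 2 adjusted over the list alone). Across the list the median was 0.32 (camera adjusted p = 0.0106, adjusted p = 0.656 with an estimated correlation). Cx3cr1, a chemokine receptor (4.24 ± 0.75), Folr2, a folate receptor of tissue macrophages (2.89 ± 0.53), and the lectin Clec4a1 (2.85 ± 0.44) rose, with edgeR adjusted p of 0.0167, 0.0161 and 0.0114, while Cd209a fell. None of the 25 LPM identity genes passed (0 adjusted over the list alone). Their median was -1.06 (camera adjusted p = 7e-06, adjusted p = 0.526 with an estimated correlation), and it reversed to 0.16 without the RE libraries of number 2 and the library labelled Ecoli SPM BAC+ 2 (camera adjusted p = 0.332). Gata6 (-0.95 ± 0.93), Timd4 (-1.81 ± 0.89) and Adgre1 (-0.13 ± 0.48) had edgeR adjusted p of 0.568, 0.233 and 0.938. Both RE LPM libraries of number 2 lay below every other LPM library for 23 of the 25 genes. B cell genes had a median of -1.25 with none passing (0 of 19 adjusted over the list alone, camera adjusted p = 2.77e-08, adjusted p = 0.407 with an estimated correlation). Erythroid and platelet genes had a median of -3.47 with none passing (6 of 9 fell, adjusted over the list alone, camera adjusted p = 0.000714, adjusted p = 0.366 with an estimated correlation). Mast cell and basophil genes had a median of -2.19 with 1 of 11 fallen (3 adjusted over the list alone, camera adjusted p = 0.0376, adjusted p = 0.526 with an estimated correlation). Immediate early genes, which can respond to sorting, had a median of -0.40 with none of 22 passing (0 adjusted over the list alone, camera adjusted p = 0.00363, adjusted p = 0.509 with an estimated correlation).

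The known targets of RA did not move together. Of 23 RA-responsive genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.786, adjusted p = 0.934 with an estimated correlation). They were Arg1, the arginase of alternatively activated macrophages (3.23 ± 0.69, edgeR adjusted p = 0.0302), and the transglutaminase Tgm2 (1.93 ± 0.35, edgeR adjusted p = 0.0161). Rarb, an RA receptor and RA target (-0.30), the RA-degrading enzymes Cyp26a1 (-0.77) and Cyp26b1 (-0.24) and the retinal reductase Dhrs3 (0.49) had edgeR adjusted p of 0.65, 0.634, 0.972 and 0.142. Libraries whose Adgre1 goes against their label lowered the values of Rarb and Cyp26a1. Cyp26a1 read 17.0 to 27.7 CPM in Ecoli LPM, 17.3 and 21.2 in RE LPM number 1 and 0.113 and 1.445 in number 2. None of the 18 retinoid metabolism genes passed (0 adjusted over the list alone, camera adjusted p = 0.933, adjusted p = 0.958 with an estimated correlation). Efferocytosis and complement genes had 3 of 24 risen (3 adjusted over the list alone), namely Nr1h3, the sterol sensor LXR alpha (3.49), Axl, a receptor for dying cells (1.41), and complement C3 (1.66). As a list they had a camera adjusted p = 0.685, adjusted p = 0.934 with an estimated correlation. Nos2 (4.47 ± 1.15), Il1b (0.65 ± 0.30) and Marco (0.06 ± 0.78) had edgeR adjusted p of 0.0533, 0.209 and 1. The lists of iron and heme, T and NK cell, inflammatory cytokine, lipid, cell cycle, unfolded protein response, alternative activation, dendritic cell, oxidative phosphorylation, mesothelial and eosinophil genes had camera adjusted p of 0.0587 to 0.933. Among these, median, mean and test direction were -0.03, 0.25 and up for alternative activation. They were 0.04, 0.04 and down for the unfolded protein response and 0.06, 0.15 and down for mesothelial genes.

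The 547 RA calls varied in number with single libraries, with counts of 31 without Ecoli LPM BAC- 1, 73 without Ecoli LPM BAC+ 1, 80 without Ecoli LPM BAC- 2 and 102 without Ecoli SPM BAC- 2. Further counts were 122 without RE LPM BAC- 2, 130 without RE SPM BAC- 2, 140 without RE LPM BAC+ 2 and 148 without RE SPM BAC+ 2. Further counts were 168 without Ecoli LPM BAC+ 2, 342 without Ecoli SPM BAC+ 1, 881 without RE SPM BAC- 1 and 1041 without RE LPM BAC+ 1. Further counts were 1618 without Ecoli SPM BAC- 1. Without the 4 RE libraries of number 2, 12 genes were called, all among the 547. Without both Ecoli SPM BAC- libraries 11 were called, 9 of them among the 547. The median size of the log2 fold change of the 547 was 1.59, and in the called direction it was 1.03 without the former and 1.21 without the latter. The RE libraries of a number deviated together. With a random block of arm and number limma called 68 genes, and with counts summed per arm and number edgeR called 0 (1552 at an unadjusted p under 0.05). Of the 44 genes named as passing, 8 passed with each of the 16 libraries left out in turn (Trem1, Treml4, Chil3, Ly6a2, Acod1, Slc16a3, Hk3 and Tlr6), and 36 lost the call in at least 1 of the 16.

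Within LPM, 4 genes rose with RA and none fell (edgeR quasi-likelihood test, 1719 at an unadjusted p under 0.05, DESeq2 416, voom 26). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), averaged 119 ± 49.2 (SD, n = 4) normalised CPM in RE and 4.64 ± 2.75 (SD, n = 4) in Ecoli, a log2 fold change of 4.78 ± 0.63. All 4 RE libraries lay above all 4 Ecoli libraries (edgeR adjusted p = 0.0478). Treml4 rose by 4.01 ± 0.58, to 24.4 ± 15.4 from 1.55 ± 0.588, and Ly6a2 by 6.24 ± 0.91, to 10.7 ± 3.74 from 0.137 ± 0.170 (edgeR adjusted p = 0.0484 and 0.0485, each in 4 of 4 libraries). The fourth was Gm16675, a predicted gene named only after its values were seen (3.33, edgeR adjusted p = 0.0484), which had 1 of 4 RE libraries above all Ecoli libraries. The LPM identity list had a median of -1.19 with none of 25 passing (1 fell, adjusted over the list alone, camera adjusted p = 2.71e-11, adjusted p = 0.59 with an estimated correlation). The monocyte list had a median of 2.15 with 1 of 16 risen (9 adjusted over the list alone, camera adjusted p = 2.41e-07, adjusted p = 0.59 with an estimated correlation). In both RE LPM libraries of number 2, whose Adgre1 goes against their label, 23 of the 25 LPM genes lay below and 9 of the 16 monocyte genes above every other LPM library. Some monocyte genes were also read more in RE LPM number 1 than in Ecoli LPM, with Treml4 at 13.9 and 8.84 against 1.06 to 2.40 normalised CPM and Ccr2 at 126 and 110.4 against 10.8 to 40.7. Lysosome and phagosome genes had a median of -0.29 with none of 35 passing (2 fell, adjusted over the list alone, camera adjusted p = 0.000553, adjusted p = 0.59 with an estimated correlation). Lyz2, lysozyme, stood at -2.06 ± 0.39 and Hexa at -1.59 ± 0.33 (edgeR adjusted p = 0.185 and 0.213). Thbd (-1.95 ± 0.51) and Dhrs3 (-0.42 ± 0.27) had edgeR adjusted p of 0.239 and 0.564. By uptake, edgeR called 1 gene in LPM BAC+ (Gm16675, named after its values were seen) and 0 in LPM BAC- (477 at an unadjusted p under 0.05, DESeq2 20, voom 0). The 1 call was lost with any RE or Ecoli LPM library left out and with voom. The 4 calls became 0 without Ecoli LPM BAC+ 1, Ecoli LPM BAC+ 2, Ecoli LPM BAC- 1, Ecoli LPM BAC- 2, Ecoli SPM BAC- 1, Ecoli SPM BAC- 2 or RE LPM BAC- 2, 1 without RE LPM BAC+ 2, RE SPM BAC+ 1 or RE SPM BAC+ 2 and 2 without Ecoli SPM BAC+ 1 or the library labelled Ecoli SPM BAC+ 2, and 0 with DESeq2's size factors in edgeR (1698 at an unadjusted p under 0.05). With the compared libraries alone edgeR called 0 (2156 at an unadjusted p under 0.05), with a random block of arm and number limma called 0 (1677), and with counts summed per arm and number edgeR called 0 (1008). None of the 4 passed with every library left out in turn.

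Within SPM, 338 genes rose with RA and 16 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, DESeq2 1864, voom 60, compared libraries alone 23). Siglec1, the sialic acid receptor of macrophages (chromosome 2, 131069220 to 131086765), averaged 147 ± 129 (SD, n = 4) normalised CPM in RE and 7.21 ± 13.3 (SD, n = 4) in Ecoli. Chil3 averaged 617 ± 260.1 and 13.6 ± 11.3, and Fcgr1 438 ± 404 and 12.1 ± 13.7, each with all 4 RE libraries above all 4 Ecoli libraries. Their log2 fold changes were 6.14 ± 1.19, 6.01 ± 0.86 and 5.90 ± 1.02, with edgeR adjusted p of 0.0247, 0.0111 and 0.0168. Ms4a4a rose by 5.61 ± 1.27 (edgeR adjusted p = 0.0418). Arg1 (5.22 ± 1.07), Treml4 (4.01 ± 0.58), Acod1 (3.51 ± 0.53) and Axl (2.68 ± 0.42) rose too, with edgeR adjusted p of 0.0111 to 0.0302. Genes that fell included Gnl3, a nucleolar GTPase that overlaps Pbrm1 (-2.27 ± 0.45), Zfp560 (-2.33 ± 0.52), Ndufaf4, an assembly factor of respiratory complex I (-2.10 ± 0.45), and Rgs2 (-2.05 ± 0.50), with edgeR adjusted p of 0.0227 to 0.0493. Dhrs3 rose by 1.40 ± 0.27 (edgeR adjusted p = 0.0221, 3 of 4 RE libraries above the Ecoli mean).

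In SPM the lowest list p were those of lysosome genes, phagocytic receptors and type I interferon genes, and no list kept its call with an estimated correlation. Lysosome and phagosome genes had 5 of 35 risen (21 adjusted over the list alone). The list median was 1.06 (camera adjusted p = 2.28e-12, adjusted p = 0.161 with an estimated correlation), with the proton pump subunit Atp6v1b2 (1.60) and the lysosomal glycoprotein Cd68 (1.57) as examples. Phagocytic and scavenger receptors had 9 of 30 risen (17 adjusted over the list alone). Their log2 fold changes had a median of 1.35 (camera adjusted p = 4.59e-12, adjusted p = 0.0877 with an estimated correlation), with Fcgr4 at 2.58. Type I interferon genes had 5 of 29 risen (17 adjusted over the list alone). The median over the list was 2.16 (camera adjusted p = 4.59e-12, adjusted p = 0.282 with an estimated correlation), with Oas3 at 4.72 and Ifi204, a DNA sensor, at 3.45. Pattern recognition genes had 6 of 29 risen (19 adjusted over the list alone). As a list they had a median of 1.30 (camera adjusted p = 9.77e-12, adjusted p = 0.116 with an estimated correlation), with Tlr4, the receptor for lipopolysaccharide, at 2.30. Antimicrobial genes had 5 of 19 risen (11 adjusted over the list alone). Across the list the median was 1.27 (camera adjusted p = 3.22e-09, adjusted p = 0.116 with an estimated correlation), with Hp at 2.59. Glycolysis genes had 3 of 23 risen (15 adjusted over the list alone). Their median was 1.06 (camera adjusted p = 3.38e-09, adjusted p = 0.161 with an estimated correlation), with Slc16a3 at 2.69. B cell genes had a median of -1.72 with none of 19 passing (0 adjusted over the list alone, camera adjusted p = 6.81e-09, adjusted p = 0.282 with an estimated correlation). Several medians were largest in SPM BAC-, where the Ecoli libraries held the most B cell RNA. There the lysosome median was 1.71 and the phagocytic receptor median 2.71, against 0.33 and 0.02 in SPM BAC+. The type I interferon medians were 2.54 and 2.05, and without the RE libraries of number 2 that of SPM was -0.03 (camera adjusted p = 0.015, direction up). By uptake, edgeR called 845 genes in SPM BAC- (701 higher, 144 lower, DESeq2 2670, voom 176). It called 0 in SPM BAC+ (522 at an unadjusted p under 0.05, DESeq2 16, voom 0). The last comparison holds the library labelled Ecoli SPM BAC+ 2, whose Adgre1 goes against its label. The 845 calls became 0 without Ecoli SPM BAC- 2, 56 without RE SPM BAC- 2, 469 without Ecoli LPM BAC- 1, 486 without Ecoli LPM BAC- 2, 490 without Ecoli LPM BAC+ 2, 498 without Ecoli LPM BAC+ 1, 2358 without Ecoli SPM BAC- 1 and 30 without the 4 RE libraries of number 2. The 354 calls became 5 without Ecoli SPM BAC+ 1, 6 without Ecoli SPM BAC- 2, 43 without RE SPM BAC- 2 and 75 without RE SPM BAC+ 2. Further counts were 181 without Ecoli LPM BAC- 1, 183 without Ecoli LPM BAC- 2, 203 without Ecoli LPM BAC+ 1 and 204 without Ecoli LPM BAC+ 2. Further counts were 853 without RE SPM BAC- 1 and 1734 without Ecoli SPM BAC- 1. Without both Ecoli SPM BAC- libraries edgeR called 0 genes in SPM (569 at an unadjusted p under 0.05), and the median log2 fold change of the 354 in the called direction was 1.02 against 2.13. There Dhrs3 read -0.07 (edgeR adjusted p = 0.992 in a range of 5.66e-06 to 0.992 over its alternatives). Without the RE libraries of number 2 edgeR called 16, all among the 354, with a median of 1.55. With a random block of arm and number limma called 231 genes in SPM, and with counts summed per arm and number edgeR called 0 (1379 at an unadjusted p under 0.05). None of the 21 genes named as passing in SPM passed with every library left out in turn.

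**Figure D4:**
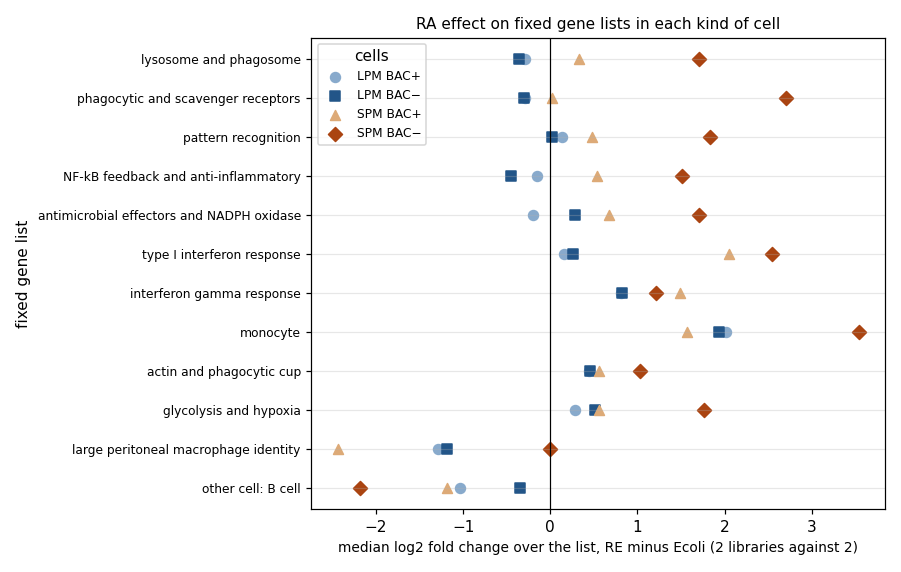
Median log2 fold change, RE minus Ecoli, of 12 gene lists (vertical axis) in LPM BAC+, LPM BAC-, SPM BAC+ and SPM BAC- (points, n = 2 libraries per arm in each), on a horizontal axis in log2 units. The lysosome list lay at -0.29, -0.36, 0.33 and 1.71, and the monocyte list at 2.01, 1.93, 1.57 and 3.55.

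SPM and LPM were compared to find which transcripts part the cell types, averaged over arm and uptake, with the library labelled Ecoli SPM BAC+ 2 kept under its label although its Adgre1 goes against it, as were both RE LPM libraries of number 2. Some cytokine, complement and retinoid genes were lower in SPM. Csf3, the granulocyte growth factor G-CSF, fell by 2.20 ± 0.32 on the log2 scale. Cxcl1, a neutrophil chemokine, fell by 2.34 ± 0.39 and C1qa, a chain of complement C1q, by 1.81 ± 0.30, each with all 8 SPM libraries below the LPM mean (edgeR adjusted p = 0.0139 for Csf3, 0.014 and 0.0139). Klf4, a transcription factor of macrophages (-1.60 ± 0.21), and Dhrs3 (-1.45 ± 0.19, 91.0 ± 60.0 against 169.6 ± 28.5 normalised CPM, n = 8 each, chromosome 4, 144892827 to 144928209) had the lowest p, with an edgeR adjusted p of 0.0105 each. Saa3, an acute phase protein, averaged 2478 ± 2165 (SD, n = 8) normalised CPM in SPM and 14540 ± 10880 (SD, n = 8) in LPM (edgeR adjusted p = 0.0414). Adgre1, on which the cells were sorted, was at 691 ± 868 against 2168 ± 1013 (-2.07 ± 0.50, edgeR adjusted p = 0.0484), a check of the sort and no finding.

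Of 15260 genes, 81 were higher and 278 lower in SPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, DESeq2 1888, voom 277). The largest among the higher genes averaging at least 3 log2 CPM were Ifi214 (3.06 ± 0.65), Cd226, an adhesion receptor (2.92 ± 0.67), and Ly6a2 (2.54 ± 0.55, with 4 of 8 SPM libraries above the LPM mean). The cyclin Ccnd2 (2.27 ± 0.41), Ly6a (1.85 ± 0.41) and Rubcnl (1.72 ± 0.35) followed. Their edgeR adjusted p were 0.0203 to 0.0457, with 7 of 8 SPM libraries above the LPM mean for all but Ly6a2. Ly6a2 and Ly6a are close paralogs, as are the Ifi200 genes around Ifi214, and stay uncertain. By the same limit, the largest among the lower genes were Epha4 (-2.99 ± 0.69), Pmp22 (-2.97 ± 0.64), Saa3 (-2.88 ± 0.66) and Adamtsl5 (-2.86 ± 0.57, 7 of 8 libraries). Pf4, platelet factor 4 (-2.85 ± 0.58), and Bmp2, a bone morphogenetic protein (-2.81 ± 0.52), followed, with edgeR adjusted p of 0.0238 to 0.0461. Across all 8 libraries a side, 7 genes were higher and 2 lower in SPM with no overlap, where chance gives 1.19 each way for independent libraries. The 2 lower symbols, A930011G23Rik and Rasgef1b, had the same values and count as 1.

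Of the LPM identity genes 5 of 25 were lower in SPM (25 adjusted over the list alone). The list median was -2.73 (camera adjusted p = 3.62e-22, adjusted p = 0.156 with an estimated correlation). Lower members included Thbd, thrombomodulin (-2.21 ± 0.36), Cd93 (-1.69) and Rarb (-1.98 ± 0.37, overlapping Top2b). Gata6 (-2.76 ± 0.98), Timd4 (-3.11 ± 0.93) and Icam2 (-2.66 ± 0.77) had edgeR adjusted p of 0.136, 0.0903 and 0.0801. Here the library labelled Ecoli SPM BAC+ 2 lay at LPM levels and the RE LPM libraries of number 2 at SPM levels. Phagocytic and scavenger receptors had 10 of 30 lower (1 higher and 19 lower, adjusted over the list alone). Their log2 fold changes had a median of -1.22 (camera adjusted p = 3.77e-15, adjusted p = 0.0212 with an estimated correlation). No other list kept its call with an estimated correlation. Its members Cd36, a scavenger receptor for lipids (-1.58 ± 0.25), the lectin Clec4d (-1.56), Cd300a (-1.10) and Cd14, a co-receptor for lipopolysaccharide (-1.49), had edgeR adjusted p of 0.0139 to 0.0215, and Marco (-3.03) of 0.0737. Lysosome genes had 6 of 35 lower (14 adjusted over the list alone). The median over the list was -0.50 (camera adjusted p = 2.24e-12, adjusted p = 0.156 with an estimated correlation). Lyz2 (-1.53 ± 0.27), Ctsl, a cathepsin (-1.55), and Hexa (-1.21) were among those lower. In Ecoli BAC-, Ecoli BAC+, RE BAC- and RE BAC+ the phagocytic receptor medians were -3.78, -0.61, -0.34 and 0.06 and the lysosome medians -2.16, -0.35, -0.13 and 0.35, so both rested mostly on Ecoli BAC-, where the SPM held the most B cell RNA. Efferocytosis and complement genes had 5 of 24 lower (1 higher and 15 lower, adjusted over the list alone). As a list they had a median of -1.34 (camera adjusted p = 4.22e-11, adjusted p = 0.138 with an estimated correlation), with C1qb at -1.67 and C1qc at -2.05. Cytokines had 10 of 30 lower and 1 higher (16 and 3 adjusted over the list alone). Across the list the median was -1.27 (camera adjusted p = 4.72e-10, adjusted p = 0.138 with an estimated correlation), with Il1a at -2.01. The cytokine median was -2.77 in Ecoli BAC-, -1.12 in Ecoli BAC+, -0.48 in RE BAC- and 0.10 in RE BAC+.

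Retinoid metabolism genes had 3 of 18 lower in SPM (2 higher and 6 lower, adjusted over the list alone). Their median was -0.67 (camera adjusted p = 0.00273, adjusted p = 0.156 with an estimated correlation). The 3 were Dhrs3, Rarb and Fabp5, a fatty acid binding protein that can carry RA (-1.63). By stratum the retinoid list median was -1.80 in Ecoli BAC-, 0.28 in Ecoli BAC+, -0.14 in RE BAC- and -0.26 in RE BAC+. NF-kB feedback genes had 3 of 23 lower (1 higher and 6 lower, adjusted over the list alone). The list median was -0.25 (camera adjusted p = 0.0023, adjusted p = 0.329 with an estimated correlation), and it reversed to 0.20 without the Ecoli SPM BAC- libraries (camera adjusted p = 0.999). These 3 were Ier3 (-1.51), the anti-inflammatory cytokine Il10 (-1.34) and the phosphatase Dusp1 (-1.24). Lipid genes had 5 of 30 lower (7 adjusted over the list alone). Their log2 fold changes had a median of -0.38 (camera adjusted p = 0.00457, adjusted p = 0.156 with an estimated correlation), with Apoe, apolipoprotein E, at -2.44 ± 0.52 and Lpl, lipoprotein lipase, at -1.16. The eosinophil chemokine Ccl24 was lower as well (-2.38 ± 0.47, edgeR adjusted p = 0.0252). On the other side, SPM and antigen presentation genes had a median of 1.26 with 1 of 24 higher (12 higher and 1 lower, adjusted over the list alone, camera adjusted p = 3.16e-05, adjusted p = 0.355 with an estimated correlation). H2-Ab1 (1.53 ± 0.50) and Ccr2 (1.83 ± 0.67) had edgeR adjusted p of 0.105 and 0.147. B cell genes had a median of 1.38 (0 of 19 passing, 15 adjusted over the list alone, camera adjusted p = 1.07e-06, adjusted p = 0.355 with an estimated correlation). Fcer1a, the IgE receptor of mast cells and basophils, stood at 4.67 ± 0.91 (edgeR adjusted p = 0.0301). The 359 calls became 61 without RE LPM BAC- 1, 66 without RE SPM BAC+ 2, 77 without Ecoli LPM BAC- 1 and 85 without Ecoli LPM BAC+ 1. Further counts were 102 without RE SPM BAC- 1, 111 without Ecoli SPM BAC+ 1, 124 without Ecoli LPM BAC- 2 and 147 without RE LPM BAC+ 1. Further counts were 153 without Ecoli LPM BAC+ 2, 191 without RE SPM BAC+ 1, 192 without RE SPM BAC- 2 and 204 without Ecoli SPM BAC- 2. Further counts were 633 without Ecoli SPM BAC- 1 and 864 without the library labelled Ecoli SPM BAC+ 2. Without both Ecoli SPM BAC- libraries edgeR called 0 (1367 at an unadjusted p under 0.05), with the median log2 fold change of the calls at 0.95 against 1.53. Without the RE libraries of number 2 and the library labelled Ecoli SPM BAC+ 2 it called 1360, 289 of them among the 359. Of 39 named calls 12 passed with every library left out in turn.

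Without RA, 85 genes were higher and 422 lower in SPM than in LPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, DESeq2 2219, voom 328). Csf3 (-3.70 ± 0.49), the antioxidant enzyme Gpx3 (-3.46 ± 0.53), Hal, histidine ammonia lyase (-3.37 ± 0.48), and Adamtsl5 (-3.42 ± 0.83, 3 of 4 libraries) had the largest falls among genes averaging at least 3 log2 CPM. Lyz2 averaged 42440 ± 41290 (SD, n = 4) normalised CPM in SPM and 153900 ± 36950 (SD, n = 4) in LPM. Cd14 (-2.81 ± 0.41), the IgG receptor Fcgr3 (-2.57 ± 0.38) and Dhrs3 (-2.37 ± 0.28) were lower too, each of these 4 genes in 4 of 4 libraries with an edgeR adjusted p of 0.00547. Trerf1 (4.74 ± 1.13), Cd226 (4.35 ± 1.01), Slamf9 (4.05 ± 0.98) and S100a6 (3.09 ± 0.76, 3 of 4 libraries) were the largest rises, with edgeR adjusted p of 0.0403 to 0.0466. They rested on single libraries and passed in 3, 1, 1 and 4 of 16 runs with a library left out. Trerf1 read 45.3 normalised CPM in Ecoli SPM BAC+ 1 and 2.17 to 9.03 in the other Ecoli SPM libraries, Cd226 377 and 5.04 to 16.6, and Slamf9 364 and 7.92 to 77.9. S100a6 read 5446 in Ecoli SPM BAC- 2 and 73.0 to 761 in the others. Ecoli SPM BAC+ 1 also held the highest eosinophil and dendritic cell sums of the Ecoli libraries. Phagocytic receptors had 12 of 30 lower (2 higher and 23 lower, adjusted over the list alone). The median over the list was -2.29 (camera adjusted p = 1.16e-20, adjusted p = 0.00741 with an estimated correlation). Lysosome genes had 13 of 35 lower (26 adjusted over the list alone). As a list they had a median of -1.05 (camera adjusted p = 1.16e-20, adjusted p = 0.079 with an estimated correlation). B cell genes had a median of 1.87 with 1 of 19 higher (12 adjusted over the list alone, camera adjusted p = 1.6e-06, adjusted p = 0.37 with an estimated correlation). Between the BAC- groups edgeR called 1314 genes (341 higher, 973 lower, DESeq2 3493, voom 1191). That count became 164 without Ecoli SPM BAC- 2, 402 without Ecoli LPM BAC- 1, 441 without Ecoli LPM BAC- 2 and 2340 without Ecoli SPM BAC- 1. Between the BAC+ groups it called 1 (Gm16675, named after its values were seen), with the library labelled Ecoli SPM BAC+ 2, whose Adgre1 goes against its label, among the SPM. The last count became 4 without that library, 0 with any other library left out and 112 (83 higher, 29 lower) without that library and the RE libraries of number 2. The 507 calls became 79 without Ecoli SPM BAC+ 1, 137 without Ecoli LPM BAC+ 1, 154 without Ecoli LPM BAC- 1 or Ecoli SPM BAC- 2 and 192 without Ecoli LPM BAC- 2. Further counts were 227 without Ecoli LPM BAC+ 2, 907 without the library labelled Ecoli SPM BAC+ 2 and 1254 without Ecoli SPM BAC- 1, and without both Ecoli SPM BAC- libraries edgeR called 1, with the median log2 fold change of the calls at 0.755 against 2.02. Of 12 named calls 7 passed with every library left out in turn.

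With RA, edgeR called 0 genes between SPM and LPM (907 at an unadjusted p under 0.05, DESeq2 67, voom 0), and 1 with the number as a replicate block nested in arm. Type I interferon genes had the lowest list p, with a median of 2.19 and none of 29 passing over all genes (25 higher adjusted over the list alone, camera adjusted p = 3.35e-25, adjusted p = 0.588 with an estimated correlation). Stat2, a transcription factor of interferon signalling (2.19 ± 0.61, 4 of 4 SPM libraries above the LPM mean), and Usp18, which dampens it (3.85 ± 1.07, 3 of 4), had edgeR adjusted p of 0.811 and 0.811. The difference rested mostly on the RE SPM libraries of number 2. Stat2 read 194 and 338 normalised CPM in these, 38.5 and 37.7 in RE SPM number 1 and 28.4 to 34.1 in RE LPM. Usp18 read 552 and 695, 30.1 and 20.2, and 18.0 to 29.1. Without the RE libraries of number 2 the type I interferon response list had a median of 0.44 (camera adjusted p = 0.0769). LPM identity genes had a median of -2.84 with none of 25 passing (0 adjusted over the list alone, camera adjusted p = 2.29e-14, adjusted p = 0.631 with an estimated correlation). Icam2 stood at -2.85 ± 1.09 (edgeR adjusted p = 0.811). Of these 25, 23 lay below every other LPM library in both RE LPM libraries of number 2.

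BAC+ and BAC- cells were compared to find what goes with uptake of bacteria. Averaged over arm and cell type, no gene passed in edgeR (0, with 1674 at an unadjusted p under 0.05, DESeq2 308, voom 0). Phagocytic receptors had a median of 1.00 (0 of 30 passing, 15 higher adjusted over the list alone, camera adjusted p = 8.58e-17, adjusted p = 0.0146 with an estimated correlation), with Cd36 at 1.18 ± 0.25. Lysosome genes had a median of 0.60 (0 of 35, 15 higher adjusted over the list alone, camera adjusted p = 8.58e-17, adjusted p = 0.105 with an estimated correlation), with Cd68 at 1.20 ± 0.23 (8 of 8 BAC+ libraries above the BAC- mean) and Lyz2 at 1.13 ± 0.27 (4 of 8). Cytokines had a median of 0.78 (0 of 30, 11 higher and 1 lower, adjusted over the list alone, camera adjusted p = 1.41e-10, adjusted p = 0.0854 with an estimated correlation), with Csf3 at 1.47 ± 0.32 and Tnf at 1.42 ± 0.31. These genes, C1qb (1.32), Dhrs3 (1.26) and the haemoglobin scavenger Cd163 (0.94) had edgeR adjusted p of 0.12 to 0.183. The list medians came mostly from Ecoli SPM. In Ecoli LPM, Ecoli SPM, RE LPM and RE SPM they were 0.11, 3.25, 0.01 and 0.49 for phagocytic receptors, 0.02, 1.89, -0.01 and 0.38 for lysosome genes and 0.41, 2.02, 0.09 and 0.65 for cytokines. B cell genes had a median of -1.16 (0 of 19, 0 adjusted over the list alone, camera adjusted p = 1.98e-11, adjusted p = 0.228 with an estimated correlation). Jchain, of antibody-secreting cells, stood at -2.29 ± 0.74 and Cpa3, of mast cells, at -3.27 ± 0.71 (edgeR adjusted p = 0.311 and 0.16). Leaving out Ecoli SPM BAC- 1 gave 63 genes in place of 0.

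In SPM, 180 genes were higher and 9 lower in BAC+ than in BAC- cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, DESeq2 1255, voom 47). Genes for scavenging and digesting cargo were among them. Cd36 (chromosome 5, 17781690 to 17888801) averaged 609 ± 196 (SD, n = 4) normalised CPM in BAC+ and 153 ± 99.7 (SD, n = 4) in BAC-. Cd68 (chromosome 11, 69664213 to 69666153) averaged 966 ± 224 and 341 ± 347, and Dhrs3 141 ± 16.1 and 41.3 ± 39.7, with edgeR adjusted p of 0.0168, 0.0157 and 0.0139 and all 4 BAC+ libraries above the BAC- mean. Among genes averaging at least 3 log2 CPM, Gdf15, a stress-induced cytokine (3.29 ± 0.52), Hal (3.13 ± 0.48), the hyaluronan receptor Lyve1 (2.95 ± 0.50) and Gas2l3 (2.85 ± 0.58) rose most, with edgeR adjusted p of 0.0142 to 0.0347. By the same limit, B3gnt5 (-2.13 ± 0.47), Zc3h12d (-2.12 ± 0.45), Twsg1 (-1.95 ± 0.42) and Stoml1 (-1.30 ± 0.28) fell most, with edgeR adjusted p of 0.038 to 0.0439. All 4 genes were highest in the SPM BAC- libraries with the most B cell RNA. In RE SPM BAC- 2 (B cell sum 1108 CPM), Zc3h12d (6.44) and Twsg1 (19.1) lay within the BAC+ range. B3gnt5 and Stoml1 lay above it.

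Phagocytic receptors had 9 of 30 higher in SPM BAC+ (19 adjusted over the list alone). Across the list the median was 1.82 (camera adjusted p = 8.02e-21, adjusted p = 0.00452 with an estimated correlation), with Clec4e, a lectin for mycobacterial glycolipid, at 1.95. Lysosome genes had 6 of 35 higher (28 adjusted over the list alone). Their median was 1.06 (camera adjusted p = 5.26e-22, adjusted p = 0.0552 with an estimated correlation), with Ctsl at 1.98 and Lyz2 at 2.18. Efferocytosis and complement genes had 5 of 24 higher (10 adjusted over the list alone). The list median was 1.86 (camera adjusted p = 3.8e-12, adjusted p = 0.0552 with an estimated correlation), with C1qa at 2.37 and C1qb at 2.38. Iron and heme genes had 3 of 19 higher (10 adjusted over the list alone). Their log2 fold changes had a median of 1.13 (camera adjusted p = 1.78e-08, adjusted p = 0.0186 with an estimated correlation). The 3 were Cd163 (2.16 ± 0.30), Slc11a1, a phagosomal metal transporter (2.18), and Nfe2l2, the regulator of the oxidative stress response (1.52). The medians were larger without RA than with it, at 3.25 and 0.49 for phagocytic receptors, 1.89 and 0.38 for lysosome genes, 3.38 and 0.30 for efferocytosis and 1.56 and 0.41 for iron and heme genes. The LPM identity list moved as far, with 3.75 and 0.86. The former stratum holds the library labelled Ecoli SPM BAC+ 2, whose Adgre1 goes against its label, on the BAC+ side. Tnf was higher as well (2.25 ± 0.45, edgeR adjusted p = 0.0346). B cell genes had a median of -2.18 with none of 19 passing (17 lower adjusted over the list alone, camera adjusted p = 3.8e-12, adjusted p = 0.187 with an estimated correlation). Their sum was 23370 and 37960 CPM in the Ecoli SPM BAC- libraries against 4298 and 1581 in Ecoli SPM BAC+. In the Ecoli arm edgeR called 637 genes (588 higher, 49 lower, DESeq2 2100). In the RE arm it called 0 (210 at an unadjusted p under 0.05, DESeq2 0, voom 0). The 637 calls became 9 without Ecoli SPM BAC- 2, 299 without the library labelled Ecoli SPM BAC+ 2, 411 without Ecoli LPM BAC- 1 and 1509 without Ecoli SPM BAC- 1, and voom gave 99. The 189 calls became 0 without RE SPM BAC- 1, 37 without Ecoli SPM BAC- 2 and 47 without Ecoli LPM BAC- 1. Further counts were 55 without RE SPM BAC+ 2, 63 without RE SPM BAC+ 1 and 67 without Ecoli LPM BAC+ 1. Further counts were 68 without Ecoli LPM BAC+ 2 or Ecoli LPM BAC- 2, 117 without the library labelled Ecoli SPM BAC+ 2 and 596 without Ecoli SPM BAC- 1. Without both Ecoli SPM BAC- libraries edgeR called 0 (258 at an unadjusted p under 0.05), with the median log2 fold change of the 189 in the called direction at 0.71 against 1.96. It also called 0 without the RE libraries of number 2 (2016 at an unadjusted p under 0.05), where that median was 2.12, and 0 with the compared libraries alone (1954). Without the library labelled Ecoli SPM BAC+ 2 it called 117, 93 of them among the 189. None of the 20 named calls passed with every library left out in turn.

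In LPM, edgeR called 0 genes by uptake (330 at an unadjusted p under 0.05, DESeq2 5, voom 0). Csf3 (0.97 ± 0.44, 3 of 4 BAC+ libraries above the BAC- mean), Cycs, cytochrome c (0.63 ± 0.57), and Cpa3 (-3.63 ± 1.04) all had an edgeR adjusted p of 1. Cytokines had a median of 0.22 (0 higher and 0 lower of 30 adjusted over the list alone, camera adjusted p = 0.00889, adjusted p = 0.946 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.17 (0 and 0 of 22, camera adjusted p = 0.019, adjusted p = 0.946 with an estimated correlation). Mesothelial genes had a median of -1.91 (2 of 15 lower adjusted over the list alone, camera adjusted p = 1.59e-08, adjusted p = 0.661 with an estimated correlation) and mast cell genes of -2.55 (0 of 11, camera adjusted p = 2.77e-05, adjusted p = 0.661 with an estimated correlation). No gene of the 4 lists passed over all genes. By arm, edgeR called 1 gene in Ecoli LPM (Gm16675, named after its values were seen), which lost its call with any of the 16 libraries left out and with voom, and 0 in RE LPM (75 at an unadjusted p under 0.05, DESeq2 0, voom 0).

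Tests of the differences between these effects called no single gene. For the RA effect in SPM minus that in LPM edgeR called 0 (1521 at an unadjusted p under 0.05, DESeq2 306, voom 0). For the RA effect in BAC+ minus that in BAC- it called 0 (544, DESeq2 1, voom 0). For the uptake effect in SPM minus that in LPM it called 0 (1303, DESeq2 138, voom 0). Phagocytic and scavenger receptors differed as a list in all 3. Their median was 1.55 for RA by cell type (16 of 30 adjusted over the list alone, camera adjusted p = 8.14e-19, adjusted p = 0.0184 with an estimated correlation). It was -1.37 for RA by uptake (0 adjusted over the list alone, camera adjusted p = 1.39e-15, adjusted p = 0.0251 with an estimated correlation). It was 1.82 for uptake by cell type (13 adjusted over the list alone, camera adjusted p = 7.93e-17, adjusted p = 0.0153 with an estimated correlation). Iron and heme genes differed for uptake by cell type, with a median of 1.06 (3 of 19 adjusted over the list alone, camera adjusted p = 6.41e-08, adjusted p = 0.0282 with an estimated correlation). Cd14 (2.65 ± 0.55) and Lyz2 (2.42 ± 0.53) for RA by cell type had edgeR adjusted p of 0.229 and 0.229. Axl (-1.93 ± 0.56) and Clec7a (-1.60 ± 0.55) for RA by uptake, and Cd163 (2.43 ± 0.41) and Cd36 (2.05 ± 0.50) for uptake by cell type had edgeR adjusted p of 1, 1, 0.226 and 0.351. Each of the 3 contrasts holds the Ecoli SPM BAC- libraries with their B cell RNA. Leaving out Ecoli SPM BAC- 1 gave 97 genes for RA by cell type and 5 for uptake by cell type.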

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

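All tests of explanations in this part were chosen after the pattern was seen, and the splits of the libraries before. Of 88 sets of libraries examined, 14 held 1 library far from the rest of its set, where a rate of 1 in 20 would give 4.4. That rate is for independent sets of like libraries. Here each set mixed BAC+ and BAC-, and many flags came from the same library, so 4.4 is no measure of chance. Most stood in the Ecoli SPM libraries. The library labelled Ecoli SPM BAC+ 2 read 45.83 normalised CPM for Gata6 (others 0.71 to 2.09), 2775 for Adgre1 (92.06 to 265), 1224 for Timd4 (26.31 to 197.6), 688.6 for Icam2 (97.24 to 168), 12.02 for Cyp26a1 (0.0789 to 1.18), 273.5 for Arg1 (3.87 to 26.4), 164.1 for Marco (2.21 to 28.5) and 2.418 for Nos2 (0 to 0.192). Ecoli SPM BAC+ 1 read 19530 for H2-Ab1 (833.6 to 3247) and 1276 for Ccr2 (68.46 to 73.99). The neutrophil sum of Ecoli SPM BAC- 2 was 13510 CPM (767.9 to 2198). In LPM, the dendritic cell sum of Ecoli LPM BAC+ 1 was 229.1 (138.7 to 138.9), Dhrs3 read 166 in RE LPM BAC+ 2 (136.8 to 140.8) and the eosinophil sum of RE LPM BAC- 2 was 56.81 (15.72 to 21.13).

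The library labelled Ecoli SPM BAC+ 2 carried LPM transcripts, Adgre1 included. A swap with an Ecoli LPM library was argued against, since 0 of the 4 Ecoli LPM libraries lacked these transcripts, and uptake as the reason too, since 0 other SPM BAC+ libraries had them. A swap with an RE LPM library of number 2 was argued against by 153 genes that separate the other 7 Ecoli and 6 RE libraries, at which both RE LPM libraries of number 2 lay on the RE side for 92.2% and 96.7%. At these genes the library labelled Ecoli SPM BAC+ 2 lay on the RE side for 55.6%, so they did not settle its arm, and the bound for the swap was set after these values were seen. LPM as only part of the library cannot be told apart from LPM as all of it. Over 20 genes at least 4 times higher in each other Ecoli SPM library, it lay at -9.12% of the way from LPM to SPM (quartiles -14.2 and -4.89), which speaks against a share of SPM. Over 197 genes at least 4 times lower there it lay 82.9% of the way to the LPM level, below the 89.5% to 106% of the Ecoli LPM libraries. A single wrong label and a swap with a library outside the series stay open, and the library whose profile was nearest was Ecoli LPM BAC- 2 (r = 0.9736).

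Both RE LPM libraries of number 2 had few LPM transcripts and more monocyte transcripts. A swap with the SPM libraries of their number was argued against, since 0 of the RE SPM libraries of number 2 carried LPM levels. RA as the reason was argued against by the RE LPM libraries of number 1, whose LPM list shifted by -0.42 from Ecoli LPM against -4.69 in number 2, or 8.96% of it. Fewer LPM and more monocyte-derived cells in the gate could not be told apart from a difference between the animals, with 56.2% of the monocyte genes above every other LPM library, because the sources give no cell counts.

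The RA calls in SPM rest on the Ecoli SPM BAC- libraries, in which macrophage transcripts such as Cd68 (89.5 and 83.1 normalised CPM) were low and B cell transcripts high. RNA of other cells in place of macrophage RNA remains a possible explanation, since the lysosome median for RA was higher by 1.38 in SPM BAC- than in SPM BAC+ (1.46 without the library labelled Ecoli SPM BAC+ 2). On low depth, Ecoli SPM BAC- 1 held 34.3 M counts, near but below the median of 36.6 M. Its lysosome genes still lay at -1.38 against the mean RE SPM BAC- library. The test asked for a depth above the median and rests on 1 library, so it cannot decide. A biological difference between SPM that took up bacteria and SPM that did not stays open and was not tested apart from RNA of other cells.

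Phagocytic and scavenger receptors differed for RA by cell type, RA by uptake and uptake by cell type, with medians of 1.55, -1.37 and 1.82. Iron and heme genes differed for uptake by cell type, with 1.06. Camera adjusted p with an estimated correlation were 0.0184, 0.0251, 0.0153 and 0.0282. The use of the estimated correlation here was chosen after the results were seen, and all 4 hold the Ecoli SPM BAC- libraries.

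For RA, averaged, 1 of 40 splits of the libraries gave as many genes as the real 547 (the highest other gave 1). Chance can be excluded for the average if the libraries are independent. In LPM 1 of 40 gave as many as the real 4 (highest other 0). The LPM libraries can be split in few ways, 2 against 2 in each uptake class, which the 40 splits repeat. So this cannot exclude chance in LPM. In RE, libraries of a number deviated together (r of 0.22 to 0.607). With a random block of arm and number limma called 68 averaged and 0 in LPM. With counts summed per arm and number edgeR called 0 and 0, so chance is not excluded for grouped libraries. For RA in SPM chance cannot be excluded, with 2 of 40 as large (real 354, highest other 395), nor for SPM against LPM, with 3 of 40 averaged (359, 870) and 7 of 40 without RA (507, 1176), nor for uptake in SPM, with 5 of 40 (189, 1418). Where the real count was 0 every split gave as many, so the 40 of 40 there say nothing about chance. The highest other was 441 for cell type with RA, 60 for uptake averaged, 0 for uptake in LPM and 0, 0 and 504 for RA by cell type, RA by uptake and uptake by cell type. A split with several times the real count, as for uptake in SPM, points to a structure of the samples, which was not tested. When the libraries of 1 arm and number were kept together, the 2 other ways to pair the sets gave 0 genes each against 547, which is too few splits for a share.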

How the results depend on the processing

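The alternatives added after the data were seen are named above. Of the values of named genes under the alternatives, 3451 kept their side of the threshold, 1375 kept the direction and lost the call, and 96 gained it. In 1 the direction reversed with a call on at least 1 side. Reversals with no call on either side are counted among the 3451. Of the values of lists, 2478 kept their side, 324 lost the call and 14 reversed in the same sense. For lists the direction is that of the camera test, which can differ from the sign of the median. Counts within 1.5 times the original are left out below, and the cause was not tested.

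DESeq2 size factors in edgeR called 0 genes for RA in LPM, and no other count moved. Without the filter the counts were 2146, 679 and 1802 for RA averaged, in LPM and in SPM, 2070, 2225 and 519 for SPM against LPM averaged, without and with RA, 669, 12 and 1490 for uptake averaged, in LPM and in SPM, and 430, 11 and 548 for RA by cell type, RA by uptake and uptake by cell type. In the same order the DESeq2 Wald test gave 2130, 416 and 1864, 1888, 2219 and 67, 308, 5 and 1255, and 306, 1 and 138. Voom with quality weights gave 360, 26 and 60 for RA, 328 for cell type without RA and 47 for uptake in SPM. With the compared libraries alone, edgeR gave 0 for RA in LPM, 23 for RA in SPM and 0 for uptake in SPM. With counts summed per arm and number it gave 0 for RA averaged, in LPM and in SPM.

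With each library left out in turn, when a group of 1 is taken to vary like the others, counts ran from 31 to 1618 for RA averaged, 0 to 3 in LPM and 5 to 1734 in SPM, from 61 to 864 for cell type averaged, 79 to 1254 without RA and 0 to 0 with RA, from 0 to 63 for uptake averaged, 0 to 0 in LPM and 0 to 596 in SPM, and from 0 to 97, 0 to 0 and 0 to 5 for the interactions. Without the RE libraries of number 2 edgeR called 12, 1 and 16 for RA, 803 for cell type without RA and 0 for uptake in SPM (2016 at an unadjusted p under 0.05), where the median fold of the original calls did not shrink (2.12 against 1.96). Without the Ecoli SPM BAC- libraries it called 11, 0 and 0 for RA, 0 and 1 for cell type averaged and without RA and 0 for uptake in SPM (1873, 569, 1367 and 258 at an unadjusted p under 0.05 for the 4 zeros). Without the RE libraries of number 2 and the library labelled Ecoli SPM BAC+ 2 it called 30, 1 and 36 for RA, 1360, 1667 and 23 for cell type, 79 for uptake in SPM and 1 for RA by cell type.

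The replicate numbers were checked for pairing. Deviations of libraries with the same number and arm correlated at 0.22 to 0.607 in RE (6 of 6 above 0.1) and -0.345 to 0.143 in Ecoli (2 of 6), and across arms at -0.355 to 0.112 (1 of 16), so RE libraries of a number deviated together, while in Ecoli and across arms libraries share only a number. With the number as a replicate block RA in LPM had 7 calls. A random block of arm and number gave 68, 0 and 231 for RA and 350 for uptake in SPM (limma). It gave 582 and 913 for cell type averaged and without RA. A block nested in arm gave 838, 1066 and 1 for cell type, 609 for uptake in SPM and 1 for RA by cell type. The nested block without the library labelled Ecoli SPM BAC+ 2 gave 1907, 2390 and 70 for cell type, 91 and 469 for uptake averaged and in SPM, 190 for RA by cell type and 10 for uptake by cell type.

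Without the Ecoli SPM BAC- libraries, the camera direction reversed for the following lists, given with their medians. For RA averaged they were phagocytic receptors (-0.0919, adjusted p = 0.369 by camera) and lysosome genes (-0.0870, 0.0919). For RA in SPM they were efferocytosis (-0.47, 0.307) and T and NK cell genes (-0.0448, 0.639). For cell type averaged they were pattern recognition (0.17, 0.757), NF-kB feedback (0.20, 0.999), iron and heme (-0.0216, 0.999) and T and NK cell genes (0.0219, 0.999). T and NK cell genes reversed for uptake averaged (0.24, 0.746), and iron and heme genes for RA by uptake (0.16, 0.634). Dhrs3 for RA in SPM reversed there as well (-0.0672, edgeR adjusted p = 0.992). The LPM list for RA averaged reversed without the RE libraries of number 2 and the library labelled Ecoli SPM BAC+ 2 (0.16, 0.332), mesothelial genes for cell type averaged without RE SPM BAC+ 1 (-0.12, 0.86, in a range of -0.12 to 2.08 with each library left out), and the SPM and antigen presentation list without Ecoli SPM BAC+ 1 for uptake averaged (-0.21, 0.423, range -0.21 to 0.78) and in SPM (-0.44, 0.21, range -0.44 to 1.42).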
